A study of Danio rerio with 6 samples.

How the data were processed

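RNA was measured by sequencing in 6 samples of adult zebrafish (Danio rerio) heart, 3 from wild-type fish (WT) and 3 from fish carrying Tg(hsp70l:DN-MAML). Per the labels, the fish were of the TU-AB strain, 6 to 12 months old and kept at 4 fish per liter. Their hearts were amputated, the fish received a daily heat shock of 1 h at 38 C, and the hearts were collected 5 days after amputation. Per the labels' protocols, RNA was extracted with the RNeasy Plus Micro Kit and libraries followed standard Illumina protocols. Per the design text, samples were collected in triplicate and sequenced on an Illumina HiSeq instrument.

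Per the submitters' processing notes, FastQC, cutadapt, STAR, featureCounts and DESeq2 were used, with no versions, roles or order stated. The genome build, the annotation and the tool that made the FPKM are not given in the sources used here. The authors deposited a table of FPKM (fragments scaled to gene length and library size) for 32105 genes in the 6 samples, rounded to 0.01. The authors also deposited a comparison table of 33737 genes. Its normalized mean count over the samples, per the file headers, carries the name DESeq2 gives it. Its log2 fold change and the standard error of that change are, per the file headers, those of a DESeq2 result, and positive values are higher in DN-MAML, as checked against the FPKM. Its score, per the file headers and as checked on the values, is the log2 fold change over its standard error. Its unadjusted p-value and adjusted p-value are the authors' own, with no value given for part of the genes. The tables share 24667 gene identifiers. Another 7438 are only in the FPKM table and 9070 only in the comparison table.

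No counts per sample were used, and the step of 1 read could not be recovered from the FPKM. The depth per sample is therefore unknown, and no counting interval is given. The FPKM add up to between 852778 and 914709 per sample. The design set before the data were examined named a count test for counts and limma for FPKM, and limma was used. Gene names came from the authors' deposited table for 24667 genes of the FPKM table and from a gene name table for another 4330. The remaining 3108 genes have an identifier only.

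FPKM were used on the deposited scale as log2(FPKM + 0.5), for the 16556 genes with a mean of at least 0.5 over the 6 samples. The added 0.5 makes fold changes of low genes smaller than the ratio of their FPKM. DN-MAML was compared with WT in limma 3.58.1 under R 4.3.3, with a trended, robust variance estimate and no block. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Errors of fold changes are limma's standard errors (SE), and FPKM are given as mean ± SD with n = 3. An exact two-sided permutation test of 3 against 3 samples cannot go below 0.1, so none is given for single genes. The labels do not say whether the samples come from separate animals or pools, so p-values measure only the spread between these samples. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

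There were 31 gene lists, fixed before the data were examined, holding 945 genes, of which 869 were matched to an identifier. Each list with at least 3 genes tested (29 lists) was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. The same lists were tested with an estimated correlation and with fry, whose directional test is meant unless its mixed test, for changes in either direction, is named. A gene's p-value was also adjusted over its list alone. After the values were seen, 1 identifier was taken out of the cell cycle list: the authors' deposited table calls it mcm5 and the gene name table calls it hsp70.1, and another identifier carries mcm5 in that list. A wider rule, tried once, keeps only identifiers with the same symbol in both tables. It takes out 10, of which 6 are merely missing from the gene name table, so it was set aside. Both this rule and no removal are among the alternatives.

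Named genes followed a rule fixed before the data were examined. It takes up to 10 of the largest rises and 10 of the largest falls among genes past the threshold whose groups do not overlap, passing over and counting clone-style or identifier-only names. From each list it takes up to 4 genes past the threshold over the list alone, or else the 2 with the smallest p as values. It always takes maml1, maml2, maml3, hsp70l, wif1 and notum1b. The symbols maml2 and notum1b matched no gene of the FPKM table. The gene called NOTUM (3 of 3) was chosen after its values were seen.

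The steps were tested on simulated data with 16556 genes, of which 200 were changed, 50 at each size. limma called 20% of the genes changed by 0.5 log2 units, 72% at 1, 100% at 2 and 96% at 3. It also called 14 unchanged genes, 8.86% of its calls and so above the 5% that the threshold aims at, and 0 when no gene was changed. camera called 0 lists when nothing was changed. It called 27 of 50 draws of the cell cycle list that had no group difference but shared an effect of single libraries. Its calls therefore need not tell a group difference from such an effect. The effect was simulated at a single size and for this list only, so the rate for other lists is unknown.

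Alternatives set beforehand were median-ratio scaling, quantile normalization, added values of 0.1 and 1, no filter and a minimum mean of 2 FPKM. Further ones were the replicate number as a block, leaving out each sample, no robust estimate, a 2-fold minimum and a threshold of 0.1. The authors' deposited table as the source of the values, and its use with and without a minimum mean count of 10, were added after the data were seen, as were the other ways of matching lists. Figures were drawn with matplotlib 3.10.9.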

Results

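The data are FPKM of 32105 genes in hearts of adult zebrafish 5 days after amputation, 3 WT samples and 3 DN-MAML samples. DN-MAML is a dominant-negative Mastermind, a truncated Notch co-activator that blocks transcription by Notch, driven by the heat shock promoter hsp70l. Between 22976 and 24094 genes had an FPKM above 0 in a sample. The mitochondrially encoded genes (13) made up 22.4% to 31.0% of the FPKM. The erythroid list made up 2.199%, 3.696% and 3.167% in WT replicates 1, 2 and 3, and 1.355%, 1.337% and 2.156% in the DN-MAML replicates. On the first principal component (36.8% of the variance), WT replicate 1 (-1.3) lay apart from WT replicates 2 and 3 (-33.8 and -25.9) and between them and the DN-MAML samples (10.1 to 28.1). Its correlation over genes was 0.978 with DN-MAML replicate 2, 0.977 with WT replicate 3 and 0.975 with WT replicate 2.

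The transgene has no entry of its own in the tables. Of the Mastermind genes, maml1 (named CT990569.2) had 3.76 ± 0.358 FPKM in WT and 4.25 ± 0.321 in DN-MAML (SD, n = 3), and maml3 had 3.06 ± 0.589 and 3.67 ± 0.434. Their log2 differences of 0.16 and 0.24 did not pass limma's test (adjusted p = 0.592 and 0.540), so the genotype labels were not checked by them. Expression of hsp70l, whose promoter drives the transgene, was 4.77, 8.10 and 73.78 FPKM in WT replicates 1, 2 and 3, and 6.84, 2.72 and 6.23 in the DN-MAML replicates (limma, adjusted p = 0.605).

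The comparison of DN-MAML with WT shows which genes differ between the groups in the regenerating heart. It does not tell effects of blocked Notch from other differences between the groups. The Notch target her6, a Hairy/Enhancer of split repressor, fell from 37.2 ± 1.75 FPKM to 18.8 ± 2.37 (SD, n = 3; log2 change -0.97, SE 0.11). The extracellular heparan sulfatase sulf2a fell from 7.49 ± 1.02 to 2.38 ± 0.319 (-1.47, SE 0.14). CNN1, a calponin that binds actin in smooth muscle, fell from 65.3 ± 4.31 to 28.6 ± 0.906 (-1.17, SE 0.09). The galectin-binding glycoprotein gene lgals3bpb rose from 17.4 ± 2.39 to 76.4 ± 20.5 (2.08, SE 0.20). The microtubule-binding ENKD1 (-2.10, SE 0.22; -3.64 with 0.1 added to the FPKM), the glutaminase gls2 (-2.03, SE 0.24; -3.12 with 0.1 added) and TNFRSF14 (11 of 12), a receptor gene numbered by its name as 1 of 12 copies, whose sequences were not compared (-3.35, SE 0.28), also fell, each to under 0.5 FPKM in every DN-MAML sample. The authors' deposited table gives log2 changes of -4.37 for ENKD1 and -3.70 for gls2. ENKD1, gls2 and TNFRSF14 (11 of 12) are among 23 genes, 8 of them past the threshold, described under Other observations. Their groups do not overlap, and they differ at least 8-fold or are listed at 0 in a group. Linked genotype or reads shared between gene copies may produce such genes, so their falls are not taken as effects of blocked Notch.

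In limma, adjusted p was 0.0377 for her6, 0.0146 for sulf2a, 0.00643 for CNN1, 0.0203 for lgals3bpb, 0.0247 for ENKD1, 0.0384 for gls2 and 0.0120 for TNFRSF14 (11 of 12). In all, 9 genes were higher and 7 lower in DN-MAML among 16556 tested, and 8 of those higher and 1 of those lower have only a clone-style name or an identifier. Of all genes tested, 3115 (18.8%) had groups that do not overlap, where chance gives 10%. At an unadjusted p under 0.05 there were 2189 genes. Leaving out WT replicate 2 gave 15 genes, 11 of them also called with all samples. Leaving out another sample moved the number called further: 180 without WT replicate 1, 4 without WT replicate 3, 11 without DN-MAML replicate 1, 4 without DN-MAML replicate 2 and 6 without DN-MAML replicate 3. Of the 180 genes, 55 (30.6%) had WT replicate 1 on the WT side of the midpoint between the group means of the other samples, where 75% to 100% of the genes called without another sample had that sample on the side of its own group. Among the 180, 14 genes did not overlap between the groups of the other samples, and differed at least 8-fold or were listed at 0 in a group. Of these, 11 had WT replicate 1 on the WT side, among them zgc:172106 (0.32 FPKM, against 4.89 to 6.07 in DN-MAML) and ENKD1 (2.07 against 0.04 to 0.07). The other 3 were nr4a3, si:ch211-250o16.4 and si:dkeyp-80d11.2. In WT replicates 1, 2 and 3, nr4a3 had 0.73, 63.61 and 64.95 FPKM, and in the DN-MAML replicates 1.17, 1.24 and 1.66. The gene atf3, not past the threshold without WT replicate 1, had 4.95, 157.9 and 143.6 in the WT replicates. Its values in the DN-MAML replicates were 4.28, 13.22 and 5.49. These comparisons and genes were chosen after seeing the data. Apart from a wrong group label, weighed under Other observations, what sets WT replicate 1 apart was not tested. The gene her6 passed in 2 of the 6 fits that left out a sample, with adjusted p from 0.0992 to 0.142 in the others (without WT replicate 2 or 3, or DN-MAML replicate 2 or 3). With all samples and no block, her6 did not pass after quantile normalization (0.0516), with no filter (0.0860) or without the robust estimate (0.0521), lgals3bpb not after median-ratio scaling (0.0630) or quantile normalization (0.0502), and gls2 not under 4 such alternatives (0.0558 to 0.0860). With the replicate number as a block, none of the genes named here passed (limma, adjusted p = 0.0796 to 0.130). The adjusted p was then 0.111 for her6, 0.126 for lgals3bpb and 0.130 for gls2. lgals3bpb passed in 3, sulf2a in 2, CNN1 in 4, ENKD1 in 2, gls2 in 1 and TNFRSF14 (11 of 12) in 4 of the 6 fits that left out a sample.

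**Figure D1:**
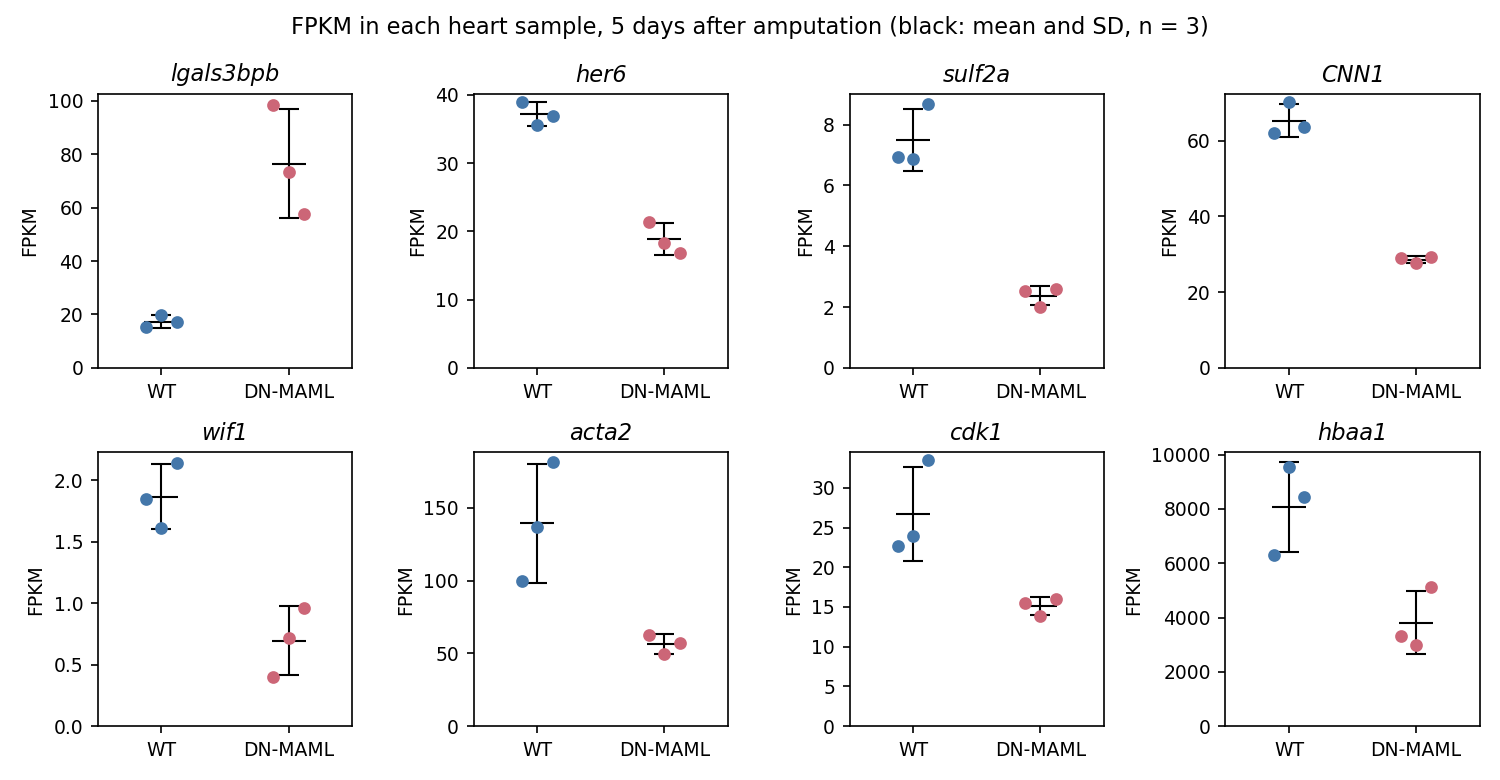
FPKM of 8 genes in each sample (points, WT in blue and DN-MAML in red), with the mean and SD of 3 samples in black and axes from 0. The genes her6, sulf2a, CNN1 and lgals3bpb passed the threshold over all genes, and wif1, acta2, cdk1 and hbaa1 passed over their own list alone.

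Among 12 Notch target genes tested, 7 were on the lower side and 5 on the higher side, and her6 was the 1 past the threshold. The authors' deposited table also gives a lower value for the Notch target hey1 (log2 change -0.93, adjusted p = 0.0326), which was under the minimum FPKM, was not tested here and is named after its values were seen. The list's median log2 change was -0.18, and it did not pass camera's test (adjusted p = 0.220). Of 9 Notch receptors and ligands tested (median 0.06), none passed, adjusted over the list alone: the endothelial ligand dll4 had 13.8 ± 0.994 and 10.4 ± 1.25 FPKM, and dld had 0.413 ± 0.268 and 1.16 ± 0.521 (SD, n = 3). Both pass in the authors' deposited table, dll4 lower (log2 change -0.42, adjusted p = 0.0260) and dld higher (1.299, adjusted p = 0.0240).

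Of 10 secreted Wnt antagonists tested, wif1, which binds Wnt proteins outside the cell, fell when adjusted over the list alone (adjusted p = 0.0131) and not over all genes (limma, adjusted p = 0.148). It had 1.87 ± 0.265 FPKM in WT and 0.693 ± 0.281 in DN-MAML (SD, n = 3; log2 change -1.01, SE 0.21). The authors' deposited table gives wif1 a log2 change of -1.31 with an adjusted p of 0.000614. wif1 was named in the design from prior knowledge of the study, whose title names Wnt pathway antagonism. The design records wif1 and notum1b as Wnt antagonists that the study is known to have drawn from these samples. How the study chose them is not stated in the deposited sources. Neither is therefore taken as independent evidence of its direction. NOTUM (3 of 3), of the family of secreted Wnt deacylases, had 15.89, 2.77 and 3.37 FPKM in the WT samples, while DN-MAML replicates 1 and 3 were listed at 0 and replicate 2 had 3.41 (limma, adjusted p = 0.401). The authors' deposited table gives NOTUM (3 of 3) a log2 change of -1.94 with an adjusted p of 5.0e-06, and gives sfrp1b, a member of the list, a log2 change of 1.32 with an adjusted p of 0.00433 (both named after their values were seen). The authors' deposited table also gives NOTUM (3 of 3) a mean normalized count of 479 over the samples. The FPKM of 0 were not reconciled with this count, so they are not taken as absent expression. Whether NOTUM (3 of 3) is notum1b was not established, so its values are not taken as independent evidence either. The list as a whole had a median of 0.46 (7 of 10 genes on the higher side; camera adjusted p = 0.343). The Wnt ligands (6 tested, median 0.25, adjusted p = 0.281) did not pass camera's test. The Wnt beta-catenin target genes (11 tested) did not pass either, with a median of 0.08, a mean of -0.04 and adjusted p = 0.989.

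Genes of the cell cycle were lower in DN-MAML, 46 of 48 tested, with a median log2 change of -0.41. Adjusted over the list alone, 13 fell, among them prc1b and anln, which act in cytokinesis, cdk1, the mitotic kinase, and cdc20, an activator of the anaphase-promoting complex. prc1b went from 13.6 ± 2.76 to 7.39 ± 0.263 FPKM and cdk1 from 26.7 ± 5.93 to 15.12 ± 1.102 (SD, n = 3). Over all genes, none of the 48 passed (limma, lowest adjusted p = 0.120). In the authors' deposited table, 17 of 49 are lower past the threshold and 0 higher, among them prc1b (adjusted p = 1.1e-05) and cdk1 (adjusted p = 0.000127). The list passed camera's test (adjusted p = 1.1e-16, adjusted p = 0.570 with an estimated correlation), and without WT replicate 3 its median was -0.24. The erythroid list was also lower in the DN-MAML group, and the leukocyte lists were higher.

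The erythroid list was lower in DN-MAML, with 21 of 22 genes on the lower side and a median of -0.65. The globin genes hbaa1 (ENSDARG00000079078, which the gene name table calls si:ch211-5k11.8; 8080 ± 1651 to 3813 ± 1156 FPKM; SD, n = 3) and ba1l (3467 ± 628 to 1613 ± 446) fell when adjusted over the list alone, as did hbbe2 and hbae5 (named hbz), both under 5 FPKM. None of the list passed over all genes, while 5 of 21 are lower past the threshold in the authors' deposited table. camera gave the list an adjusted p of 5.6e-09 (adjusted p = 0.570 with an estimated correlation).

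Genes of contraction, oxidative phosphorylation and glycolysis were slightly lower, while the leukocyte lists were higher and the erythroid list lower. In the sarcomere list 23 of 28 genes were on the lower side (median -0.15), and the ventricular myosin vmhc (319 ± 25.4 to 198 ± 37.0 FPKM; SD, n = 3), csrp3 and the M-band gene myom1a fell when adjusted over the list alone. In the oxidative phosphorylation list 67 of 71 genes were on the lower side (median -0.20), with 0 past the threshold over the list alone. The mitochondrially encoded genes made up 24.2%, 28.2% and 22.4% of the FPKM in WT replicates 1, 2 and 3 and 27.8%, 31.0% and 25.5% in the DN-MAML replicates, a difference that was not tested. In the oxidative phosphorylation list cox4i1l (named CU855779.1) had 1813 ± 231 and 1400 ± 129 FPKM, and atp5mea (named atp5ia) had 293 ± 26 and 207 ± 50.4. Glycolysis had 24 of 35 on the lower side (median -0.15), where the muscle phosphoglycerate mutase pgam2 (493 ± 35.17 to 353 ± 13.9) fell when adjusted over the list alone. camera's adjusted p was 1.0e-05 for the sarcomere list, 6.0e-14 for oxidative phosphorylation and 0.00157 for glycolysis (adjusted p = 0.570 with an estimated correlation for each). Quantile normalization ended the glycolysis call (adjusted p = 0.0768), whose median was -0.09 without WT replicate 1, and the oxidative phosphorylation median was -0.12 without DN-MAML replicate 3. Fatty acid oxidation had a median of 0.04 over 32 genes (adjusted p = 0.989), where echs1 had 110 ± 3.39 and 91.2 ± 12.6 and hadhab 94.3 ± 6.05 and 82.9 ± 1.12 FPKM.

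Genes of the interferon response were higher in DN-MAML in all 31 tested, with a median of 0.51. Adjusted over the list alone, 4 rose: ifi44a1 (11.3 ± 2.64 to 23.3 ± 5.00 FPKM; SD, n = 3), ifit9, the cytokine signalling inhibitor socs1b, and the immunoproteasome subunit psmb9a (9.21 ± 1.59 to 13.8 ± 1.37). None passed over all genes, while 10 of 35 are higher past the threshold in the authors' deposited table. camera's adjusted p was 2.3e-08 (adjusted p = 0.570 with an estimated correlation). The median was 0.24 without DN-MAML replicate 3 and 0.87 without DN-MAML replicate 2, whose score (-0.26) was lower than that of WT replicate 3 (-0.09).

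Markers of leukocytes were higher with them. The pan-leukocyte list was higher in all 12 genes tested (median 0.32), with fcer1g at 22.2 ± 4.25 and 31.8 ± 5.25 FPKM and rac2 at 23.5 ± 3.59 and 30.3 ± 0.335 (SD, n = 3). Among lymphocyte genes (14 of 16 on the higher side, median 0.46), the B cell genes cd37 (1.71 ± 0.188 to 2.99 ± 0.427) and cd79b rose when adjusted over the list alone. Among macrophage genes (21 of 23, median 0.31) c1qa had 43.8 ± 3.95 and 65.6 ± 9.72 and c1qc 84.6 ± 7.38 and 117 ± 16.8, and among neutrophil genes (10 of 13, median 0.34) cpa5 had 2.93 ± 0.168 and 4.51 ± 0.962 and lyz 4.00 ± 1.63 and 6.00 ± 0.993. For c1qc the authors' deposited table gives a mean normalized count of 0.58, which was not reconciled with its FPKM. Of the inflammatory cytokines (19 of 26, median 0.24), 5 rose and 1, the prostaglandin synthase ptgs2b, fell when adjusted over the list alone, and the chemokine gene ccl38.6 went from 3.22 ± 0.294 to 8.997 ± 2.02. camera's adjusted p was 1.1e-04, 6.9e-04, 4.7e-04, 0.0349 and 6.3e-04 in the order of these lists (adjusted p = 0.570 with an estimated correlation for each). Without WT replicate 2 the medians were 0.18 for the pan-leukocyte, 0.13 for the macrophage and 0.21 for the neutrophil list, and without WT replicate 1 the macrophage median was 0.50. The neutrophil call ended without WT replicate 3 (adjusted p = 0.337) and without DN-MAML replicate 1 (0.203), and the lymphocyte call with a minimum mean of 2 FPKM (0.0638).

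**Figure D2:**
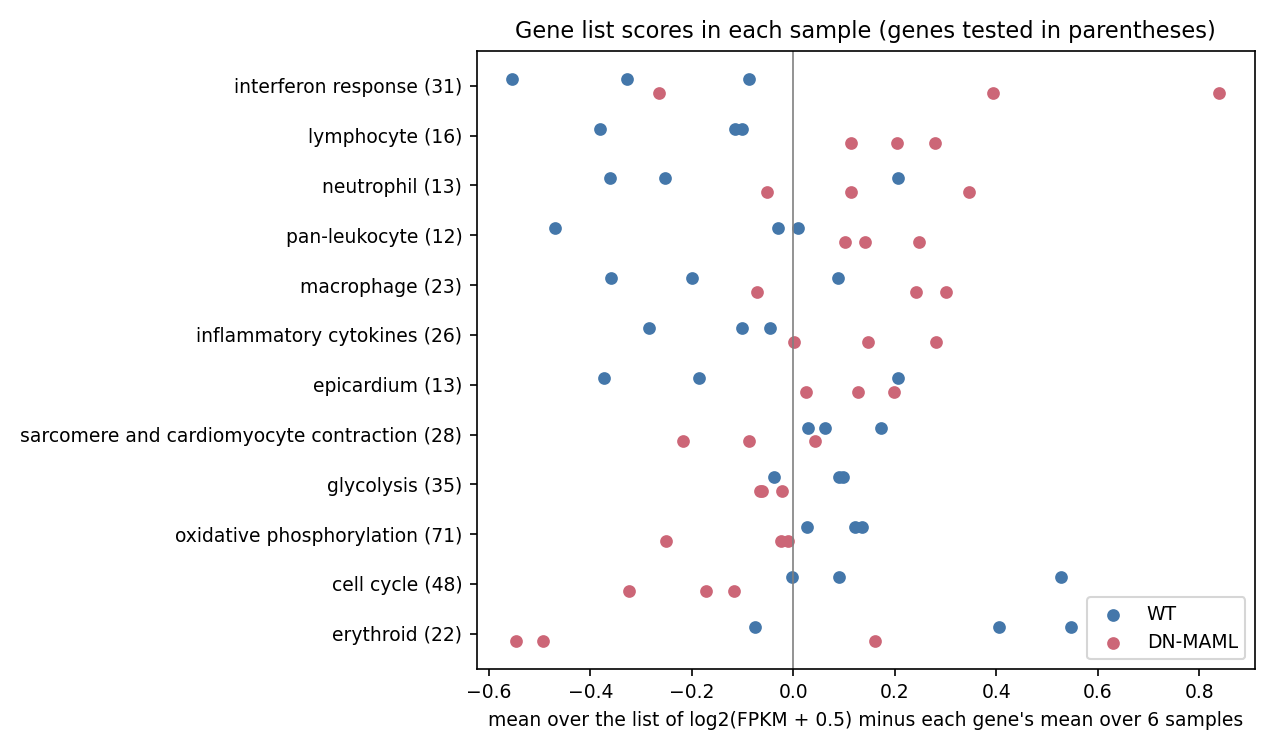
Score of the 12 lists past camera's threshold in each sample (points, WT in blue and DN-MAML in red). A score is the mean over the list of log2(FPKM + 0.5) minus each gene's mean over the 6 samples, with the number of genes tested in parentheses. The groups overlap for the interferon, neutrophil, macrophage, epicardium, sarcomere, glycolysis and erythroid lists.

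Epicardial genes were higher in 12 of 13 (median 0.20), and the keratin krt4 rose when adjusted over the list alone, from 142 ± 37.0 to 241 ± 19.9 FPKM (SD, n = 3). camera gave this list an adjusted p of 0.0223 (adjusted p = 0.570 with an estimated correlation). The call ended without WT replicate 2 (median 0.09, adjusted p = 0.122), without WT replicate 3 (0.0973) and without DN-MAML replicate 2 (0.238). Without WT replicate 1 the median was 0.33. It did not pass camera on the statistics of the authors' deposited table where the mean count was at least 10 (adjusted p = 0.0521). In the vascular activation list (28 tested, median 0.03, mean -0.06, camera adjusted p = 0.989), E-selectin (sele) rose when adjusted over the list alone, from 17.2 ± 2.38 to 31.7 ± 2.23 (limma over all genes, adjusted p = 0.0715). In the smooth muscle list (8 tested, median 0.06, mean -0.04, camera adjusted p = 0.941), smooth muscle actin acta2 fell when adjusted over the list alone, from 139 ± 40.8 to 56.3 ± 6.72 (limma over all genes, adjusted p = 0.121). On the statistics of the authors' deposited table this list was lower past camera's threshold where the mean count was at least 10, a test chosen after seeing the data (15 genes, median -0.06, adjusted p = 0.0292). The 8 genes tested here do not include CNN1, and cnn1b, which is on the list, was not matched to the FPKM table. The authors' deposited table gives cnn1b a log2 change of -1.19 with an adjusted p of 3.7e-15, where CNN1 had -1.17 here. Of the list's 15 genes there, 2 are lower and 0 higher past the threshold. Whether CNN1 and cnn1b are the same gene was not established, so the median of 0.06 leaves out both. The endocardium and endothelium list had a median of 0.08 over 40 genes (camera adjusted p = 0.614), with the tight junction gene cldn5a at 3.60 ± 0.180 and 7.17 ± 2.00 and plvapb (named vsg1) at 18.9 ± 0.750 and 26.9 ± 4.55.

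In BMP and TGF-beta signalling (33 tested, median 0.09, camera adjusted p = 0.332), 4 genes rose and 2 fell when adjusted over the list alone. The signal transducers smad9 (8.23 ± 0.524 to 12.6 ± 0.575 FPKM; SD, n = 3) and smad1 (15.9 ± 0.775 to 22.4 ± 2.26) rose, as did the ligand bmp6, and the ligand tgfb3 fell (91.8 ± 8.88 to 66.3 ± 8.45). The list of cardiomyocyte mitogens and receptors had a median of 0.19 over 23 genes (adjusted p = 0.108), with igf2b at 27.3 ± 3.41 and 37.7 ± 4.78 and ptch1 at 4.08 ± 0.397 and 3.10 ± 0.235. The list of cardiac transcription and fetal genes had a median of -0.06 over 16 genes (adjusted p = 0.343), with mef2aa at 36.4 ± 3.68 and 26.6 ± 2.42 and gata6 at 73.2 ± 4.63 and 58.2 ± 3.69. The list of fibroblast and extracellular matrix genes had a median of -0.10 over 43 genes (adjusted p = 0.424), with hapln1a at 26.5 ± 6.29 and 14.4 ± 3.15 and tgfbi at 3.98 ± 0.448 and 4.85 ± 0.145.

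Of the 29 lists tested, 7 were higher and 5 lower past camera's threshold, and none passed with an estimated correlation or by fry's directional test (limma, lowest adjusted p = 0.234). fry's mixed test, named after its values were seen, takes changes in either direction. Its adjusted p was 4.8e-04 for inflammatory cytokines, 0.0022 for BMP and TGF-beta and 0.0028 for sarcomere genes. It was 0.0146 for both lymphocyte genes and secreted Wnt antagonists, and 0.0170 for Notch target genes. For the vascular activation and neural lists it was 0.0288, and no other list was under 0.05. On simulated data camera called 27 of 50 draws of the cell cycle list that held no group difference but shared an effect of single libraries. The rate for other lists is unknown. With none passing at an estimated correlation either, camera's calls are taken only as descriptions of the 6 samples.

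In the authors' deposited table, 384 genes were higher and 413 lower at an adjusted p under 0.05. Of these, 575 were tested here, 570 had the same direction and 546 also had an unadjusted p under 0.05 in limma. Across the 7510 genes of both tables with a mean of at least 5 FPKM, which are not independent replicates, the log2 fold changes had a correlation of 0.899. For 20 of these genes the log2 fold changes differed by over 1. Both tables were deposited for the same samples, so shared directions and calls are not independent support. All 11 genes called here that have an adjusted p in the authors' deposited table passed the threshold there in the same direction. Of the other lists past camera's threshold here, the table has past its own 3 higher in macrophage, 2 higher in lymphocyte, 3 higher and 1 lower in inflammatory cytokine, 1 higher in epicardium, 1 higher and 3 lower in sarcomere and 4 lower in glycolysis genes, and 0 in the neutrophil, pan-leukocyte and oxidative phosphorylation lists.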

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

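The comparison with the authors' deposited table, the tests on its statistics and the other ways of matching lists were chosen after seeing the data. The 9 higher and 7 lower genes became 5 and 5 with quantile normalization, 5 and 4 with a minimum mean of 2 FPKM, which tests fewer genes, 19 and 20 at a threshold of 0.1, and 384 and 413 in the authors' deposited table. Leaving out 1 sample gave 3 to 76 genes higher and 1 to 104 lower, the highest without WT replicate 1. Of the 16 genes, 10 were kept under median-ratio scaling, 10 under quantile normalization, 10 with no filter, 9 with the minimum of 2, 16 without WT replicate 1 and 3 without DN-MAML replicate 2. Except where stated, the cause was not tested. Kept past the threshold were her6 in 7 of 15 alternatives, lgals3bpb in 9 of 15 and gls2 in 4 of 14. The 12 lists became 0 with an estimated correlation and 0 by fry's directional test (lowest adjusted p 0.570 and 0.234), and were 10 to 13 without 1 sample and 12 under both other ways of matching. On the authors' statistics the smooth muscle list passed (adjusted p 0.0292, and 0.0211 on all genes). All 12 kept their direction under every alternative run. Scaling moved the median log2 change of all genes by less than 0.1. The count test was not run, as no counts were used and whole reads were not recovered. Depth per sample is unknown, so what it limits was not measured.

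With the replicate number as a block, 0 genes were higher and 0 lower (limma), and 12 lists passed. Same-numbered samples had correlations of 0.208, -0.0264 and 0.14, and the other pairs had -0.224 to 0.0943. The highest values were of same-numbered samples, but not every sample correlated best with its own number. With so few samples this neither shows nor excludes that the numbers pair the samples. Under the block the test's direction turned for smooth muscle (median 0.061) and heat shock (-0.01).

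Lists not past the threshold turned direction in the test as follows, with their medians; the cause was not tested. Notch receptors and ligands gave 0.035 with median-ratio scaling, -0.0036 with quantile normalization and -0.0099 with a minimum of 2 FPKM. Vascular activation gave -0.006705, -0.010, 0.026 with no filter and 0.026 by fry. Heat shock gave -0.044 with median-ratio scaling, 0.080 with quantile normalization, -0.013 with the minimum and -0.013 by fry. Fatty acid oxidation gave 0.0048 with median-ratio scaling and smooth muscle 0.043 with quantile normalization. Wnt beta-catenin targets gave 0.018 with no filter, 0.087 with the minimum and 0.079 by fry. With no filter, secreted Wnt antagonists gave -0.00952 and neural genes 0.025. On the authors' statistics with a mean count of at least 10, the medians were 0.039 for Wnt targets, 0.014 for vascular activation, -0.044 for heat shock, -0.0041 for fatty acid oxidation, 0.090 for liver and 0.24 for neural genes. On all their genes they were -0.15 for secreted Wnt antagonists, -0.017 for Wnt targets, 0.0085 for vascular activation, -0.044 for heat shock, -0.0059 for fatty acid oxidation and 0.14 for neural genes.

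Leaving out 1 sample, medians ranged from -0.022 to 0.097 for Notch receptors and ligands, -0.057 to 0.11 for Wnt targets, -0.11 to 0.13 for vascular activation, -0.081 to 0.12 for heat shock, -0.00799 to 0.065 for fatty acid oxidation, -0.020 to 0.24 for smooth muscle, -0.32 to 0.13 for fibroblast genes and -0.022 to 0.13 for endothelium. The log2 changes of tfa and buc ranged from -0.46 to 0.099 and -0.25 to 0.0045.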

Other observations

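The list-split count and the leave-one-out test of the interferon and erythroid lists were set before their results were seen; the gene-split count, the tests of the on or off genes, of room and of leukocytes, both tests of hsp70l, the side on which each sample lies and the chromosome counts were chosen only after.

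Of the 41 heat shock and unfolded protein genes tested (median -0.01, camera adjusted p = 0.989), none passed over the list alone; fkbp4, a co-chaperone of steroid receptors, had 155 ± 18.1 FPKM in WT and 361 ± 162 in DN-MAML, and hsph1 had 57.6 ± 11.7 and 120 ± 44.1 (SD, n = 3). In the authors' deposited table, 3 of 41 are higher past the threshold. The thrombocyte list (12 tested, median 0.00, mean -0.24, adjusted p = 0.281) held gp1bb at 15.5 ± 2.77 and 9.10 ± 1.91 and gp9 at 8.89 ± 3.12 and 4.403 ± 1.323. Among the lists for other tissues, liver, gut and pancreas had a median of 0.24 over 5 genes (adjusted p = 0.734), with hp, which the gene name table calls msmbl, at 10.4 ± 0.880 and 12.4 ± 1.43 and tfa at 127 ± 52.7 and 103 ± 1.65. The neural, glia and pigment list had a median of -0.14 over 8 genes (adjusted p = 0.550), where tubb2b fell when adjusted over the list alone, from 127 ± 14.2 to 89.0 ± 9.10. The oocyte list, with 2 genes tested, was too short to test: h1-10 (named h1fx) had 19.99 ± 4.754 and 27.5 ± 1.84, and buc 0.627 ± 0.196 and 0.547 ± 0.153.

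The 6 samples make 10 splits into 3 and 3, so a share under 0.05 is impossible. The real split gave 16 genes and the highest of the others 3, so 1 of the 10 gave as many. At an unadjusted p under 0.05 it gave 2189 genes, and the others up to 1377 (WT replicate 1 with DN-MAML replicates 1 and 3), where 0.05 of the genes tested would be 828. It gave 12 lists, and the highest of the others, WT replicate 1 with DN-MAML replicates 1 and 2, gave 14, so 2 of the 10 gave as many.

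A set of 23 genes lay in groups that do not overlap and either differed at least 8-fold in mean FPKM or were listed at 0 in all samples of a group, 14 higher and 9 lower in DN-MAML, against at most 9 in another split. A stretch of genotype linked to the transgene may produce such genes, but only 8 of the 23 (34.8%) could be placed in the gene order of GRCz12tu, so this test is void; those placed made 0 neighbouring pairs. Reads shared between gene copies may also do so: 69.6% of the 23 have clone-style, numbered-copy or identifier-only names, against 24.4% of the other genes tested (Fisher's exact test, two-sided, p = 6.3e-06), though a name is only a proxy for a copy. The other genes were not matched for expression level, and the share does not tell shared reads from linked genotype. Of the 23, 11 have an adjusted p in the authors' deposited table, and 10 of them pass there. An effect of blocked Notch on these genes was not tested and stays open.

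The interferon and leukocyte lists were higher and the erythroid list lower in DN-MAML. Less blood leaves more room for other genes, but the room is 0.021 log2 units, 0.0404 of the interferon median, which argues against it as the cause. A single library may carry part of the pattern: without DN-MAML replicate 3 the interferon median was 0.465 of its value with all samples (0.24 against 0.51). More leukocytes in the DN-MAML samples cannot be told apart from higher expression within them: the lowest DN-MAML pan-leukocyte score lay 0.0913 above the highest WT score, which restates the pattern and decides nothing, with its most abundant genes, lcp1 and fcer1gl, at 52.9 and 54.3 FPKM in WT and 62.3 and 59.8 in DN-MAML. An effect of blocked Notch within the cells was not tested and stays open.

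WT replicate 3 had 73.78 FPKM of hsp70l, against 4.77 and 8.10 in the other WT samples. A wrong group label of WT replicate 3 is argued against by the 4 genes past the threshold without it, for which 100% had WT replicate 3 on the WT side (for WT replicate 1 this was 30.6% of 180 genes, but 11 of the 14 on or off genes among them, chosen without that sample, had it on the WT side, which argues against a wrong label there too). A heat shock or stress closer to collection may have raised it, and this cannot be told apart from other sources: the other 20 inducible chaperones had a median log2 difference of 0.39, with 6 at 1 or more, among them hsp70.3 (4.88, 5.03 and 17.70 FPKM in WT replicates 1, 2 and 3) and hsp70.1 (1.46, 2.97 and 17.05). Part of the difference is shared with WT replicate 2: hspb9, also among the 6, had 5.06, 52.77 and 41.63 and bag3 28.4, 107.1 and 104.4. In the DN-MAML replicates hspb9 had 6.07, 5.26 and 8.94 and bag3 34.3, 39.05 and 43.27, near WT replicate 1. For these genes, genotype and a stress of WT replicates 2 and 3 cannot be told apart. No biological explanation was tested, as the design gives none for a single WT sample.

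Genes past the threshold in the authors' deposited table were counted by chromosome for 3 gene sets and 25 chromosomes of GRCz12tu, 75 pairs in all, of which 3 had an adjusted p under 0.05 (hypergeometric test): chromosome 1 held 19 of 168 genes over 2-fold (adjusted p = 0.0161) and 9 of 54 over 1.5 log2 units (0.0240), and chromosome 19 held 40 of 594 (0.0287). The genes counted were 656 on chromosome 1 and 588 on chromosome 19. Chromosome 5, with the most (852), held 8 of the 168 and 2 of the 54. The gene sets are nested, so the results for chromosome 1 are not separate. Among all 594, it held 39 (hypergeometric test, adjusted p = 0.187). Whether a stretch of genotype linked to the transgene lies behind these counts was not tested. Neighbouring copies of a gene family are not independent in such a count.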
